A study of Mus musculus with 58 samples.

How the data were processed

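RNA sequencing was carried out on prefrontal cortex of Tbl1xr1 knock-in heterozygous (HT) and wild-type (WT) C57BL/6J mice of both sexes at postnatal day 25. Per the labels' protocols, the pups received fluoxetine, lithium or vehicle through the milk of their mothers from day 3 to day 24, that is for 3 weeks, and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The 58 libraries fell into 12 groups of genotype, drug and sex. Each group held 5 libraries, except the females and the males of WT lithium, which held 4 each. Groups and replicate numbers were taken from the sample titles. The labels describe mice but do not state that each library is a separate animal, so p-values measure the spread between libraries. They give neither dam nor litter, and as each drug came through the milk, differences between litters are not separated from the effects of the drugs in any test here.

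The deposited table holds 18088 genes, and its values are a signal on a linear scale, namely read counts that the authors divided by 1 size factor per library. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 were used with the mouse genome build GRCm38. How reads that match several genes were shared out is not given in the sources used here. Within each library, every value was a whole multiple of 1 step at a tolerance of 0.0001, so whole reads were recovered for 100% of the values. The recovered reads came to between 22.9 and 35.01 M per library, with a median of 26.72 M, and the size factors ran from 0.7872 to 1.2293. Gene names, positions, GC content and lengths came from GENCODE release M21 on GRCm38, which matched 18077 of the gene IDs, 15253 of them protein-coding. The other 11 IDs had no name and were counted but not named.

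Differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1) for the 16606 genes with a mean of at least 10 over all libraries. A fold change on this scale understates the change of genes with low values. One model with the 12 group means was fitted to all 58 libraries, leaving 46 residual degrees of freedom, and p-values were adjusted over genes by the Benjamini-Hochberg method at 0.05. A gene is said to have risen, fallen or been called when it passed this threshold. The comparisons were HT against WT under vehicle, each drug against vehicle within each genotype, the difference of each drug effect between genotypes (interaction) and the difference of each effect between the sexes. Apart from the last, every comparison is the mean of the female and the male difference with equal weight, and the effect within each sex was also tested. Errors of log2 changes are standard errors of this model. Differences from the respective reference group are also given as the number of libraries that lay on that side of the mean of the same-sex reference group.

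Before the data were examined, 33 gene lists were written down for brain cell types, synapses, neuronal activity, stress responses, mitochondria, ribosomes and the pathways of both drugs. They were tested in 7 comparisons, the 5 effects and both interactions, with the competitive test camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. The same test with a correlation estimated from the residuals is given beside each call. Lists were also tested in the sex differences and between the drugs, and those tests were chosen after the values were seen.

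The rule for genes named in the text was also fixed beforehand. It takes Tbl1xr1 always, then for each effect the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean of at least 50. It adds the 3 members with the smallest p of each list past the threshold, and for each interaction and sex difference the 3 called genes with the smallest p. Where no gene passed, the 3 with the smallest p are given as values. Some genes that the rule takes are left out of the text. Predicted genes and clones were passed over for naming, and where 5 or fewer genes were called, those outside the rule were named after their values were seen. Reads of ribosomal protein genes can be shared with their processed pseudogenes, Ifit3 and Ifit3b are near-identical copies, and Pcdhga12 shares exons with its gene cluster, so the values of these genes are uncertain.

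The alternatives tried were pseudocounts of 0.5 and 5, a minimum mean of 50 and no minimum, upper-quartile rescaling, centring on the median, limma array weights, only the groups of a comparison, each sex alone, and covariates for striatal, choroid plexus and leptomeningeal genes. Also tried were the replicate number as a block and, on the recovered reads, the quasi-likelihood test of edgeR 4.0.16 on 17757 genes and DESeq2 1.42.0. Each library of a comparison was left out in turn. After the data had been seen, a covariate from 10 olfactory bulb genes, the removal of each library's trend on GC content and transcript length by splines with 4 degrees of freedom, and the removal of the library with the highest olfactory bulb score from each group were added, as was the removal of 2 libraries with high choroid plexus genes from the tests of that list. Replicates of a group were compared by a chi-square test of their recovered reads, which gave between 6.32 and 42.74 per degree of freedom for the pairs, so no library was counted as a repeat of another.

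The steps were tested on simulated reads with known changes, drawn from the means, spreads and library sizes of the real data. Each share rests on about 50 genes per fold and is given as the range over 20 draws. In the simulated genotype comparison, between 22% and 44% of genes changed by 1.15-fold were called, 54% to 75.5% at 1.3-fold, 74% to 90% at 1.5-fold and 85.7% to 100% at 2-fold. In that of the fluoxetine interaction the ranges were 6% to 28%, 38.8% to 58%, 61.2% to 78% and 77.6% to 98%. In that of the sex difference of fluoxetine in WT they were 2% to 14%, 20% to 42%, 34.7% to 67.3% and 66% to 86%. In these 3 comparisons between 0 and 12 unchanged genes were called per draw. Figures were drawn with Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9.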

Results

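Prefrontal cortex of mice at postnatal day 25 was sequenced as 58 libraries, in 12 groups of 2 genotypes, 3 treatments and 2 sexes. TBL1XR1 is a WD40-repeat subunit of the NCoR and SMRT corepressor complexes, which carry histone deacetylase activity to nuclear receptors, and the mice carried a knock-in allele of its gene on 1 chromosome (HT) or none (WT). Fluoxetine, a serotonin reuptake inhibitor, and lithium, a mood stabiliser that inhibits GSK3 and inositol phosphatases, reached the pups through maternal milk. There were 5 libraries per group, and 4 in each of the WT lithium groups. The group means of recovered reads lay between 25.88 M in WT fluoxetine males and 29.43 M in HT lithium females. Libraries are named by group and replicate number, values are normalised read counts with SD, and changes are on the log2(value + 1) scale with SE.

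The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y and the X-inactivation transcript Xist were read as a check of the labels. Xist was between 13378.1 and 32283.2 in the 29 females and at most 53.7 in the 29 males. Ddx3y was at least 1377.6 in every male and at most 66.7 in the females, where the highest value was that of HT lithium female 3. Every library thus lay on the side of its labelled sex.

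Tbl1xr1 (ENSMUSG00000027630, chromosome 3, 22076652 to 22216594, plus strand, GRCm38) was higher in HT than in WT under each treatment. Under vehicle its normalised read count was 2118 ± 50.3 (SD, n = 5) in WT females and 2111 ± 74.5 in WT males, against 2553 ± 90.6 in HT females and 2625 ± 85 in HT males. The lowest HT vehicle library had 2420 and the highest WT vehicle library 2220, so these groups did not overlap. With fluoxetine the means were 1946 ± 120 and 2072 ± 189 in WT females and males, and 2463 ± 146 and 2546 ± 143 in HT. With lithium they were 2107 ± 71 and 2067 ± 148 in WT, with n = 4 each, and 2475 ± 111 and 2509 ± 35.2 in HT. The gene total therefore did not fall in the animals with the knock-in allele, and reads of the altered and the normal allele were not told apart here. Neither drug changed Tbl1xr1 at the threshold, with log2 changes of -0.049 ± 0.034 and -0.077 ± 0.034 for fluoxetine in HT and WT, and -0.055 ± 0.034 and -0.020 ± 0.036 for lithium.

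The effect of the genotype alone was read from the vehicle groups, and 3 genes rose in HT. Tbl1xr1 rose by 0.29 ± 0.034, or 1.224-fold, in 10 of 10 libraries (limma adjusted p = 2.25e-07). Its X-linked paralog Tbl1x (chromosome X, 77511013 to 77662983, plus strand), which encodes another subunit of the same complexes, rose by 0.18 ± 0.030, or 1.133-fold, in 10 of 10 libraries (adjusted p = 0.00107). The long noncoding RNA Gm43672 (chromosome 3, 22074412 to 22076142, minus strand), which is transcribed away from Tbl1xr1 and ends short of its first base, rose by 0.40 ± 0.061, or 1.32-fold, in 10 of 10 libraries (adjusted p = 0.000234). Gm43672 lies outside the naming rule and was named after its value was seen. No gene fell among the 16606 tested.

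The list of the NCoR/SMRT corepressor complex, with 11 measured members, was shifted upward in HT, and 10 of its members lay above 0. Tbl1xr1 and Tbl1x rose, also when adjusted over the list alone, and the histone deacetylase Hdac4 had 0.13 ± 0.053 without passing. The camera test gave an adjusted p = 4.58e-05, and an adjusted p = 0.0135 with an estimated correlation, which among the 62 list calls of the 7 comparisons is the only one that held. Since both called genes are members, the list was tested again without them: its unadjusted p was 0.00167 without Tbl1xr1 and 0.0808 without Tbl1xr1 and Tbl1x.

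**Figure D1:**
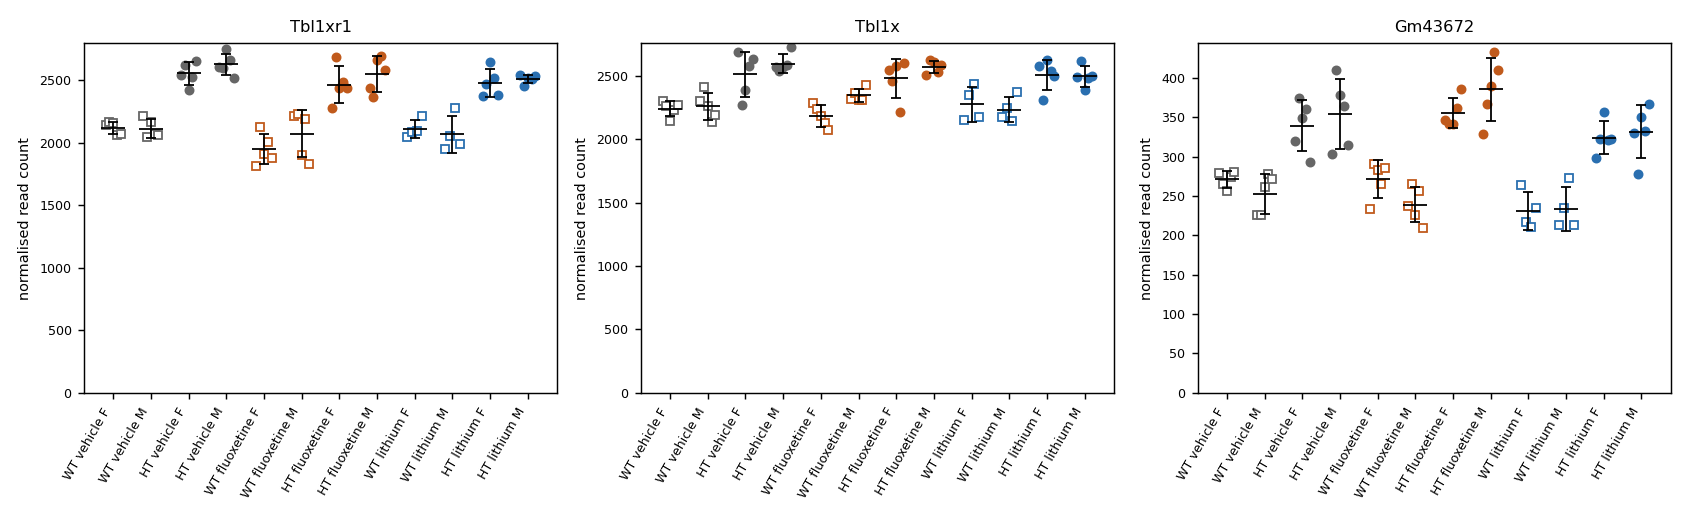
Normalised read counts (vertical axes, from 0) of Tbl1xr1, Tbl1x and Gm43672 in each library of the 12 groups (horizontal axes), with HT as filled circles and WT as open squares, and vehicle in grey, fluoxetine in orange and lithium in blue. Bars are the mean ± SD, and the mean of Tbl1xr1 is 2553 in HT vehicle females against 2118 in WT vehicle females.

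Microglial genes, which mark the resident macrophages of the brain, were shifted upward in HT, with 13 of 14 members above 0 and P2ry12 at 0.23 ± 0.096 and C1qb at 0.13 ± 0.065 (adjusted p = 7.31e-05, and adjusted p = 0.62 with an estimated correlation). Genes of the unfolded protein and integrated stress response had 17 of 18 members above 0, among them Herpud1 at 0.14 ± 0.058, Dnajb11 at 0.083 ± 0.041 and Dnajb9 at 0.071 ± 0.039 (adjusted p = 7.59e-05, and adjusted p = 0.62 with an estimated correlation). All 19 presynaptic genes lay above 0 (adjusted p = 0.000978, and adjusted p = 0.62 with an estimated correlation). The complexin Cplx2 had 0.19 ± 0.095, Syn1 0.076 ± 0.041 and Syn2 0.084 ± 0.047. Among glucocorticoid response genes 10 of 14 were above 0 (adjusted p = 0.0474, and adjusted p = 0.62 with an estimated correlation). Zbtb16 had 0.26 ± 0.090, Sgk1 0.14 ± 0.070 and Nfkbia 0.14 ± 0.079. The mitochondrially encoded mRNAs had 12 of 13 members above 0 (adjusted p = 0.00927, and adjusted p = 0.755 with an estimated correlation). mt-Nd4l had 0.49 ± 0.240, mt-Nd3 0.22 ± 0.138 and mt-Atp6 0.34 ± 0.219.

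In the other direction, all 10 choroid plexus genes were below 0 in HT, with a median of -0.48 and with Prlr at -0.68 ± 0.441, Aqp1 at -0.79 ± 0.533 and Tmem72 at -0.35 ± 0.253 (adjusted p = 0.0117, and adjusted p = 0.755 with an estimated correlation). The choroid plexus lies in the ventricles and is not part of the cortex, and WT vehicle female 4 had 413 for Prlr and 670.7 for Tmem72 where the next library of its group had 20.8 and 114.4. Without this library the adjusted p of the list was 0.956, and in males alone the list lay upward (adjusted p = 0.919), where the sex difference had an adjusted p = 0.00346, and adjusted p = 0.801 with an estimated correlation. Leptomeningeal and collagen genes had 3 of 14 members above 0 (adjusted p = 0.041, and adjusted p = 0.806 with an estimated correlation). Nupr1 had -0.37 ± 0.102, Igfbp2 -0.29 ± 0.105 and Fmod -0.20 ± 0.097. The list of serotonin receptors, transport and breakdown had 3 of 15 above 0 (adjusted p = 0.0474, and adjusted p = 0.173 with an estimated correlation). Htr5b had -0.55 ± 0.207, Htr1f -0.31 ± 0.136 and Htr1d -0.37 ± 0.279. Outside the NCoR/SMRT list, no member of these lists passed over all genes, and adjusted over the list alone only 1 leptomeningeal gene fell.

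limma called 3 genes for the genotype, all higher, with 957 genes at an unadjusted p under 0.05, edgeR called 3 and DESeq2 9. Within each sex 2 genes were called, 1 higher and 1 lower in females and 2 higher in males, and leaving out any 1 library gave 3 or 4. Array weights and the removal of the GC and length trend each gave 6 genes.

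The effect of fluoxetine in HT mice was asked against HT vehicle, and no gene passed the threshold. The values with the smallest p were -0.97 ± 0.201 for Gkn3, a gastrokine gene expressed in brain arteries, in 10 of 10 libraries (adjusted p = 0.0806), 0.099 ± 0.022 for the nucleic acid-binding protein gene Cnbp in 10 of 10 (adjusted p = 0.123), and 0.63 ± 0.142 for the kinase gene Map3k6 in 10 of 10 (adjusted p = 0.123). The immediate early genes, whose transcripts follow neuronal firing, were shifted downward together: 18 of 20 were below 0, with a median of -0.52. Npas4 had -0.77 ± 0.199, Arc -1.35 ± 0.375 and Btg2 -0.64 ± 0.183, below the HT vehicle mean in 9, 10 and 10 of 10 libraries (camera adjusted p = 3.47e-11, and adjusted p = 0.39 with an estimated correlation). Arc was 1840 ± 567 and 1060 ± 589 in HT fluoxetine females and males, against 4720 ± 2860 and 3690 ± 2170 with vehicle. Adjusted over the list alone, 10 of the 20 immediate early genes fell, and over all genes none did.

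Vessel genes lay lower in fluoxetine-treated HT mice. All 9 mural cell genes, of pericytes and arterial smooth muscle, were below 0 (adjusted p = 0.000266, and adjusted p = 0.39 with an estimated correlation). Acta2 had -0.42 ± 0.117, Myh11 -0.31 ± 0.096 and Pdgfrb -0.19 ± 0.060. Of 13 endothelial genes 4 lay above 0, with Kdr at -0.34 ± 0.119 and Cdh5 at -0.19 ± 0.069, and with the glucose transporter Slc2a1 at 0.29 ± 0.083 in the other direction (adjusted p = 0.0168, and adjusted p = 0.693 with an estimated correlation). Oligodendrocyte precursor genes had 1 of 10 above 0 (adjusted p = 0.0174, and adjusted p = 0.647 with an estimated correlation). Gpr17 had -0.26 ± 0.097, Neu4 -0.17 ± 0.095 and Olig2 -0.21 ± 0.124. Upper-layer neuron genes had 3 of 10 above 0 (adjusted p = 0.0168, and adjusted p = 0.573 with an estimated correlation). Pou3f2 had -0.21 ± 0.059, Pou3f3 -0.17 ± 0.057 and Rorb -0.22 ± 0.084. Adjusted over the list alone, 4 mural, 2 endothelial and 3 upper-layer genes fell and 1 endothelial gene rose.

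Cholesterol synthesis genes and SREBP2 targets had 2 of 21 members above 0 (adjusted p = 3.48e-05, and adjusted p = 0.647 with an estimated correlation). Insig1 had -0.14 ± 0.065. The unfolded protein response list had 3 of 18 above 0 (adjusted p = 0.00181, and adjusted p = 0.647 with an estimated correlation). Dnajb11 had -0.12 ± 0.041, Calr -0.13 ± 0.047 and Hspa5 -0.21 ± 0.089. In males Calr had -0.28 ± 0.067 and Hspa5 -0.44 ± 0.126, while females had 0.025 ± 0.067 and 0.022 ± 0.126 and their list lay upward (adjusted p = 0.163). The sex difference of this list had an adjusted p = 4.98e-10, and adjusted p = 0.312 with an estimated correlation. Of 30 autism risk genes 8 lay above 0 (adjusted p = 0.0221, and adjusted p = 0.693 with an estimated correlation). Tcf4 had -0.12 ± 0.049, Adnp -0.19 ± 0.081 and Ank2 -0.082 ± 0.039. Upward shifts were seen in the glucocorticoid response, with 10 of 14 above 0, Map3k6 as above, Fkbp5 at 0.43 ± 0.128 and Plin4 at 0.68 ± 0.288 (adjusted p = 0.00176, and adjusted p = 0.407 with an estimated correlation). Cytosolic ribosomal proteins had 66 of 81 above 0, with Rpl17 at 0.17 ± 0.052 and Rpl36a at 0.16 ± 0.061 but Rpl13 at -0.20 ± 0.079 (adjusted p = 8.82e-06, and adjusted p = 0.749 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 72 of 78 above 0 (adjusted p = 3.38e-14, and adjusted p = 0.631 with an estimated correlation). Sdhb had 0.13 ± 0.035, Ndufc2 0.16 ± 0.048 and Atp5g3 0.15 ± 0.047. In females alone the ribosomal list lay downward (adjusted p = 0.163), and its sex difference had an adjusted p = 4.89e-15, and adjusted p = 0.553 with an estimated correlation. Adjusted over the list alone, 2 glucocorticoid response genes and 1 of oxidative phosphorylation rose.

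limma called 0 genes here, with 1526 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 18. Leaving out 1 library gave 2 genes without HT fluoxetine female 4 or HT fluoxetine male 5, 1 without HT vehicle female 4, HT vehicle male 1 or HT vehicle male 3, and 0 without any other. In females limma called 1 gene, and in males 0, with 1555 there at an unadjusted p under 0.05 and 0 by edgeR and by DESeq2.

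In WT mice fluoxetine changed 61 genes, of which 26 rose and 35 fell. The effect had r = 0.227 with GC content across genes, 0.295 in females and -0.006 in males. Removing GC and length trends left fewer calls. The largest rise was that of Map3k6, a MAP kinase kinase kinase gene of the glucocorticoid response list, by 0.91 ± 0.142 in 10 of 10 libraries (adjusted p = 0.00082). Its normalised read count was 62.4 ± 11 and 71.4 ± 34.7 in vehicle females and males, and 121.9 ± 16.9 and 122.9 ± 22.2 with fluoxetine. Fkbp5, a co-chaperone of the glucocorticoid receptor and one of its targets, rose by 0.60 ± 0.128 in 10 of 10 libraries (adjusted p = 0.0193), from 849 ± 72.1 and 941 ± 195 to 1210 ± 170 and 1530 ± 335. In the glucocorticoid response list 13 of 14 genes lay above 0, 2 rose over all genes and 5 adjusted over the list alone, and Zbtb16 had 0.35 ± 0.090 (adjusted p = 3.36e-06, and adjusted p = 0.125 with an estimated correlation).

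Further genes that rose were Zc2hc1c by 0.47 ± 0.11, Pglyrp1 by 0.43 ± 0.104, the kinase gene Nek10 by 0.41 ± 0.086, the Notch glycosyltransferase gene Lfng by 0.38 ± 0.081, the neurotensin receptor gene Ntsr1 of deep-layer neurons by 0.38 ± 0.086 and the phospholipase gene Plcd3 by 0.31 ± 0.069. Their adjusted p-values lay between 0.0187 for Nek10 and 0.0436 for Pglyrp1, and 10 of 10 libraries showed the direction, or 8 of 10 for Plcd3. Ebf1, a transcription factor gene, fell by 0.52 on the log2 scale, Calcrl, the calcitonin receptor-like gene of vessels, by 0.40 and the netrin receptor gene Unc5c by 0.36. Rbm41 fell by 0.33, the delta-tubulin gene Tubd1 by 0.31, the cadherin gene Cdh10 by 0.29, Srbd1 by 0.29 and the chaperonin-like gene Mkks by 0.28. Their standard errors lay between 0.049 for Mkks and 0.122 for Ebf1, their adjusted p-values between 0.00415 for Mkks and 0.0445 for Tubd1, and 9 of 10 libraries showed the fall of Ebf1 and of Rbm41 and 10 of 10 that of the others.

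In the unfolded protein and integrated stress response list, 3 genes fell. Calr, the calreticulin gene, fell by 0.25 ± 0.047 in 8 of 10 libraries (adjusted p = 0.00923), Hsp90b1 by 0.18 ± 0.042 in 9 of 10 (adjusted p = 0.0391) and the disulfide isomerase gene Pdia6 by 0.24 ± 0.059 in 8 of 10 (adjusted p = 0.0496). In this list 5 of 18 genes lay above 0, 3 fell over all genes and 8 adjusted over the list alone (adjusted p = 4.18e-07, and adjusted p = 0.627 with an estimated correlation). Mural cell genes had 1 of 9 above 0 and 3 fell adjusted over the list alone (adjusted p = 0.00556, and adjusted p = 0.627 with an estimated correlation). Myh11 had -0.35 ± 0.096, Rgs5 -0.31 ± 0.104 and Acta2 -0.34 ± 0.117. Immediate early genes had 1 of 20 above 0 (adjusted p = 0.0401, and adjusted p = 0.929 with an estimated correlation). Homer1 had -0.37 ± 0.150, Egr3 -0.24 ± 0.137 and Nr4a3 -0.39 ± 0.260. Cholesterol genes had 3 of 21 above 0 and 1 fell adjusted over the list alone (adjusted p = 0.000674, and adjusted p = 0.929 with an estimated correlation). Stard4 had -0.18 ± 0.052, Sqle -0.13 ± 0.047 and Hmgcs1 -0.17 ± 0.067. Ribosomal protein genes had 73 of 81 above 0 (adjusted p = 3.18e-12, and adjusted p = 0.84 with an estimated correlation). Rpl17 had 0.17 ± 0.052, Rps24 0.15 ± 0.050 and Rpl14 -0.13 ± 0.045. Oxidative phosphorylation had 64 of 78 above 0 (adjusted p = 3.36e-06, and adjusted p = 0.929 with an estimated correlation). Ndufa4 had 0.13 ± 0.043, Atp5l 0.15 ± 0.052 and Uqcrq 0.17 ± 0.059. Apart from the 5 genes said to have risen or fallen, no member of these lists passed over all genes.

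**Figure D2:**
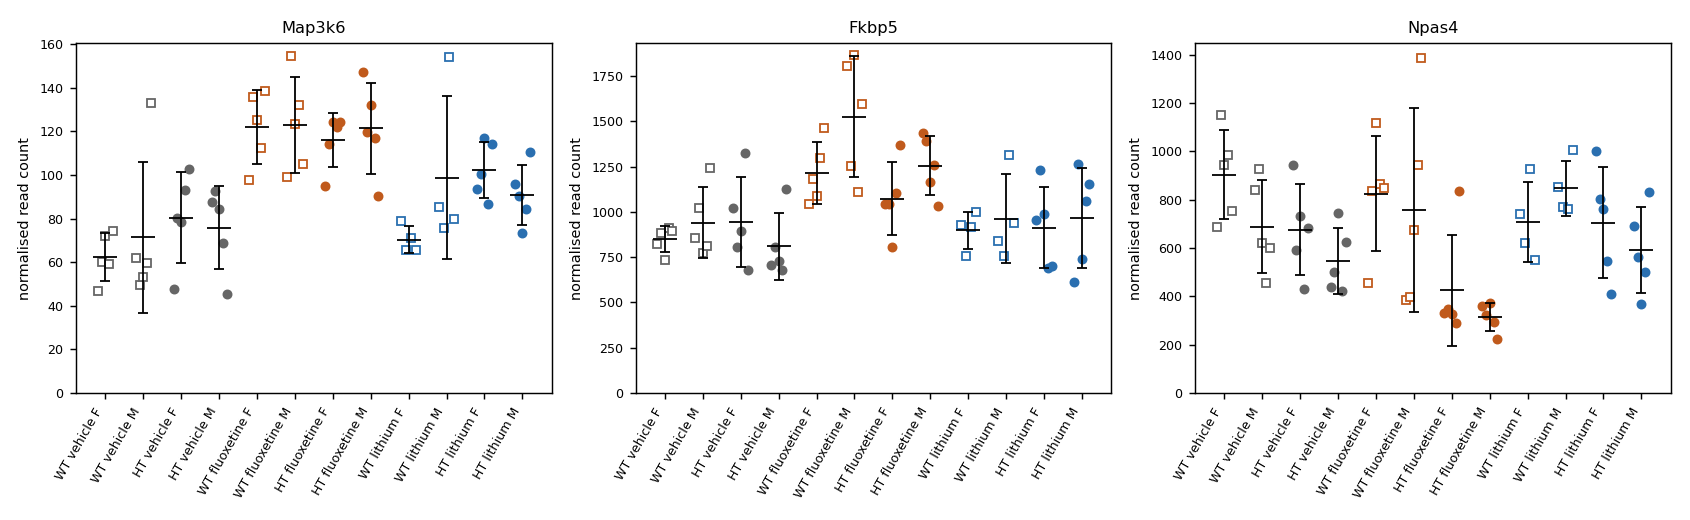
Normalised read counts (vertical axes, from 0) of Map3k6, Fkbp5 and Npas4 in each library of the 12 groups, with symbols and colours as in the earlier figure. Bars are the mean ± SD, and Map3k6 has a mean of 122 in WT fluoxetine females against 62.4 in WT vehicle females.

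limma called 61 genes for fluoxetine in WT (2221 at an unadjusted p under 0.05), edgeR 57 and DESeq2 229. Upper-quartile rescaling gave 22 higher and 47 lower genes, and over 18 alternatives the count ran from 0 in males alone to 859 with array weights. Without 1 library it was 18 without WT fluoxetine female 5 or WT vehicle male 2, 22 without WT fluoxetine male 5, 24 without WT fluoxetine female 3, WT fluoxetine male 3 or WT vehicle female 1, 29 without WT vehicle female 5, 30 without WT fluoxetine female 4, 32 without WT fluoxetine male 2, 34 without WT vehicle female 2 or WT vehicle male 3, 92 without WT vehicle female 4, 175 without WT fluoxetine female 1 and 347 without WT fluoxetine male 1.

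Within WT females fluoxetine changed 155 genes, of which 102 rose and 53 fell, and edgeR called 160 and DESeq2 447. With the trend of each library on GC content and length removed, 2 of these 155 genes were still called. In WT males limma called 0, with 1199 at an unadjusted p under 0.05, edgeR 0 and DESeq2 2. The female minus male difference itself passed for 3 genes, all higher in females. They were the zinc finger gene Zfp771 with 0.69 ± 0.129 (adjusted p = 0.0201), the transmembrane protein gene Tmem121 with 0.80 ± 0.151 (adjusted p = 0.0201) and Fam171a2 with 0.40 ± 0.079 (adjusted p = 0.0324). Zfp771 was 291 ± 18.7 with vehicle and 404 ± 54.1 with fluoxetine in females, and 354 ± 31.9 and 301 ± 29.5 in males. Tmem121 was 271 ± 24.6 and 414 ± 57.7 in females, and 347 ± 25.2 and 302 ± 39.7 in males, so both went opposite ways in the sexes.

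For that difference limma called 3 genes (1782 at an unadjusted p under 0.05), edgeR 3 and DESeq2 13, and 0 were left with the dissection covariates, the olfactory bulb covariate, the GC and length trend removed or only the groups of the comparison. Leaving out 1 library gave 0 without WT fluoxetine female 3, 4 or 5, WT fluoxetine male 3, WT vehicle female 1 or 2 or WT vehicle male 4, 1 without WT fluoxetine male 1 or 2, WT vehicle female 4 or WT vehicle male 5, 5 without WT fluoxetine female 1, 8 without WT vehicle female 3 and 52 without WT vehicle male 2.

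Lithium changed 64 genes in HT mice, of which 28 rose and 36 fell. Ctnnb1 (chromosome 9, 120929216 to 120960507, plus strand), which encodes beta-catenin, fell by 0.26 ± 0.037 in 10 of 10 libraries (adjusted p = 6.39e-05). Its normalised read count went from 18840 ± 1870 and 18340 ± 1030 in vehicle females and males to 15550 ± 769 and 15460 ± 1000 with lithium. Vegfc, a growth factor gene of lymphatic vessels, fell by 0.47, the urea transporter gene Slc14a1 by 0.47, the acylethanolamine-forming Napepld by 0.27, Basp1 by 0.26, Pcdhga12 by 0.26, the polyglutamine-binding Pqbp1 by 0.25 and the neuronal splicing factor gene Celf4 by 0.23. These falls had standard errors between 0.045 for Pqbp1 and 0.105 for Slc14a1, adjusted p-values between 0.00555 for Pqbp1 and 0.0311 for Napepld, and held in 10 of 10 libraries.

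Among the genes that rose with lithium in HT, Car12, a carbonic anhydrase gene, rose by 0.65 ± 0.150, Ung, a DNA repair glycosylase gene, by 0.61 ± 0.147, Yjefn3 by 0.49 ± 0.114, Dnhd1 by 0.48 ± 0.104, the GTPase gene Rab34 by 0.44 ± 0.102, the elongation factor gene Tcea2 by 0.30 ± 0.067 and the stress-induced Sesn2 by 0.26 ± 0.063. Ppif, which encodes the mitochondrial cyclophilin D, rose by 0.24 ± 0.041 (adjusted p = 0.00137). The other adjusted p-values lay between 0.0204 for Dnhd1 and 0.0348 for Ung and Sesn2, and 9 of 10 libraries were above the reference for Car12, Yjefn3, Tcea2 and Sesn2 and 10 of 10 for the rest.

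With lithium in HT 71 of 78 oxidative phosphorylation genes lay above 0, with a median of 0.091. Atp5g3 rose by 0.20 ± 0.047 and Ndufb5 by 0.12 ± 0.028, each in 10 of 10 libraries, while Ndufc2 had 0.19 ± 0.048, and adjusted over the list alone 21 rose and 1 fell (adjusted p = 6.76e-18, and adjusted p = 0.44 with an estimated correlation). Of 81 ribosomal protein genes 58 lay above 0, Rps15a rose by 0.16 ± 0.035 and Rpl14 fell by 0.22 ± 0.045, and Rpl22l1 had 0.27 ± 0.077. Adjusted over the list alone, 2 rose and 1 fell (adjusted p = 0.000858, and adjusted p = 0.806 with an estimated correlation). The list lay downward in females alone (adjusted p = 7.32e-05) and upward in males. Its sex difference had an adjusted p = 2.43e-36, and 0.255 with an estimated correlation. That difference had r = 0.16 with log2 length over all genes, so a library length trend stays open. The glucocorticoid response had 11 of 14 above 0, with Ddit4 at 0.32 ± 0.099, Map3k6 at 0.34 ± 0.142 and Sult1a1 at 0.38 ± 0.163, and 1 rose adjusted over the list alone (adjusted p = 0.0132, and adjusted p = 0.44 with an estimated correlation). All 10 choroid plexus genes lay above 0 (adjusted p = 0.0101, and adjusted p = 0.63 with an estimated correlation). Prlr had 0.64 ± 0.441, Clic6 0.79 ± 0.551 and Sostdc1 0.54 ± 0.382. HT lithium male 1 held the highest values of these 3 genes in its group, and without it the adjusted p of the list was 0.52.

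Synaptic genes were shifted downward in the same comparison. The presynaptic list had 4 of 19 above 0, with Syn1 at -0.16 ± 0.041, Rims1 at -0.42 ± 0.11 and Vamp2 at -0.096 ± 0.031 (adjusted p = 0.00685, and adjusted p = 0.63 with an estimated correlation), and the excitatory postsynapse 3 of 20 (adjusted p = 0.00514, and adjusted p = 0.44 with an estimated correlation). Dlgap1 had -0.13 ± 0.041, Nlgn3 -0.055 ± 0.021 and Grin1 -0.066 ± 0.033. Of 30 autism risk genes 7 lay above 0, and Ctnnb1 fell while Tcf4 had -0.14 ± 0.049 and Ank2 -0.11 ± 0.039 (adjusted p = 0.000229, and 0.44 with an estimated correlation). Upper-layer neuron genes had 1 of 10 above 0 (adjusted p = 0.00237, and 0.44 with an estimated correlation). Rorb had -0.27 ± 0.084, Pou3f2 -0.16 ± 0.059 and Calb1 -0.18 ± 0.079. Perineuronal net genes had 2 of 10 above 0 (adjusted p = 0.0334, and 0.44 with an estimated correlation). Ptprz1 had -0.16 ± 0.069, Hapln1 -0.15 ± 0.068 and Ncan -0.058 ± 0.028. Microglial genes had 2 of 14 above 0 (adjusted p = 0.0115, and 0.69 with an estimated correlation). Cx3cr1 had -0.24 ± 0.073, P2ry12 -0.22 ± 0.096 and Csf1r -0.11 ± 0.051. Endothelial genes had 3 of 13 above 0 (adjusted p = 0.018, and 0.659 with an estimated correlation). Kdr had -0.35 ± 0.119, Cdh5 -0.17 ± 0.069 and Cldn5 -0.20 ± 0.094. Mural cell genes had 1 of 9 above 0 (adjusted p = 0.0101, and 0.44 with an estimated correlation). Acta2 had -0.38 ± 0.117, Rgs5 -0.25 ± 0.104 and Myh11 -0.20 ± 0.096. Adjusted over the list alone, 3 presynaptic genes, 2 of upper layers and 1 each of microglia, mural cells, autism risk and the postsynapse fell, and 1 presynaptic gene rose.

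limma called 64 genes for lithium in HT (2030 at an unadjusted p under 0.05), edgeR 63 and DESeq2 183, and within each sex limma called 1 in females and 0 in males (1615 at an unadjusted p under 0.05), against 1 and 8 by edgeR and 6 and 46 by DESeq2. Without HT lithium male 3 the count was 25, without HT lithium female 5 it was 26, and without HT vehicle male 2 or HT vehicle male 4 it was 36.

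In WT mice lithium changed 5 genes. Ctnnb1 fell by 0.19 ± 0.039 in 8 of 8 libraries (adjusted p = 0.0374), from 17810 ± 515 and 18650 ± 1080 in vehicle females and males, with n = 5 each, to 16120 ± 948 and 15770 ± 718 with lithium, with n = 4 each. Ppp1r21, a gene of endosome traffic, fell by 0.16 ± 0.031 and the clone gene 2810013P06Rik by 0.25 ± 0.050, each in 8 of 8 libraries (adjusted p = 0.0374 for both). Atf4 (chromosome 15, 80255184 to 80257541, plus strand), the transcription factor gene of the integrated stress response, rose by 0.19 ± 0.039 in 7 of 8 libraries (adjusted p = 0.0392), and Ccdc43 by 0.18 ± 0.036 in 8 of 8 (adjusted p = 0.0374). 2810013P06Rik lies outside the naming rule and was named after its value was seen.

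**Figure D3:**
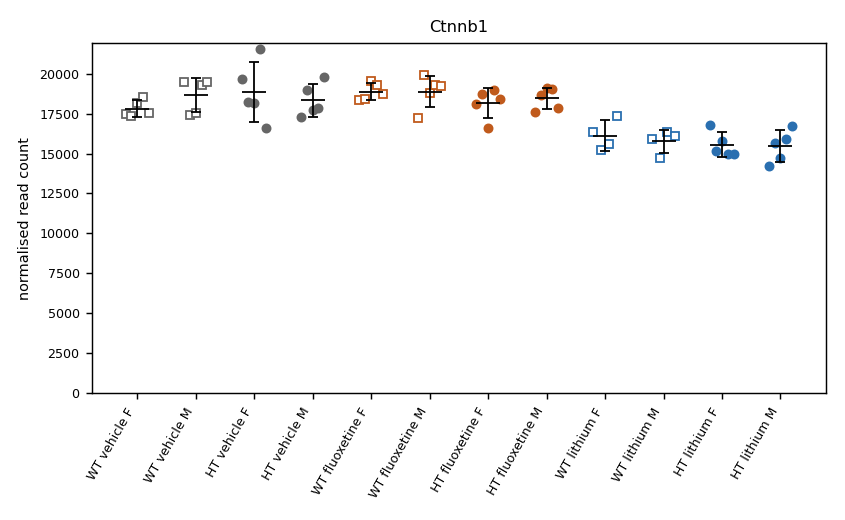
Normalised read counts of Ctnnb1 (vertical axis, from 0) in each library of the 12 groups, with symbols and colours as in the earlier figures. Bars are the mean ± SD, and the lithium means lie between 15460 and 16120 against vehicle means between 17810 and 18840.

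The unfolded protein and integrated stress response list had 17 of 18 genes above 0 with lithium in WT, with Atf4 called, Chac1 at 0.20 ± 0.074 and Ddit3 at 0.18 ± 0.084, and 1 rose adjusted over the list alone (adjusted p = 0.000928, and adjusted p = 0.715 with an estimated correlation). Interferon response genes had 2 of 17 above 0, with Ifit3b at -0.74 ± 0.221, Oas1a at -0.70 ± 0.225 and Ifit3 at -0.48 ± 0.207, and 2 fell adjusted over the list alone (adjusted p = 5.26e-05, and adjusted p = 0.715 with an estimated correlation). Immediate early genes had 17 of 20 above 0 (adjusted p = 0.0119, and adjusted p = 0.854 with an estimated correlation). Bdnf had 0.33 ± 0.116, Fosl2 0.57 ± 0.235 and Nr4a3 0.54 ± 0.276. The glucocorticoid response had 11 of 14 above 0, with Ddit4 at 0.38 ± 0.105, Nfkbia at 0.29 ± 0.084 and Sgk1 at 0.23 ± 0.074, and 3 rose adjusted over the list alone (adjusted p = 0.000661, and adjusted p = 0.684 with an estimated correlation). Oxidative phosphorylation had 72 of 78 above 0 (adjusted p = 1.11e-08, and adjusted p = 0.715 with an estimated correlation). Ndufab1 had 0.18 ± 0.051, Ndufs5 0.17 ± 0.052 and Atp5h 0.098 ± 0.035.

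Several cell type lists were shifted downward with lithium in WT. Mural cell genes had 1 of 9 above 0, with Acta2 at -0.44 ± 0.124, Pdgfrb at -0.18 ± 0.064 and Myh11 at -0.27 ± 0.102, and 3 fell adjusted over the list alone (adjusted p = 0.00746, and adjusted p = 0.715 with an estimated correlation). Endothelial genes had 2 of 13 above 0 (adjusted p = 0.0467, and adjusted p = 0.854 with an estimated correlation). Kdr had -0.30 ± 0.127, Vwf -0.17 ± 0.076 and Slc2a1 0.18 ± 0.088. None of the 10 oligodendrocyte precursor genes lay above 0 (adjusted p = 0.04, and adjusted p = 0.715 with an estimated correlation). Cspg4 had -0.20 ± 0.081, Bcan -0.076 ± 0.049 and Pdgfra -0.077 ± 0.062. Microglial genes had 4 of 14 above 0 (adjusted p = 0.0467, and adjusted p = 0.854 with an estimated correlation). Cx3cr1 had -0.22 ± 0.077, Trem2 -0.22 ± 0.095 and Siglech -0.21 ± 0.096. Leptomeningeal genes had 3 of 14 above 0 (adjusted p = 0.0467, and adjusted p = 0.854 with an estimated correlation). Fmod had -0.22 ± 0.103, Col6a3 -0.24 ± 0.133 and Ogn -0.22 ± 0.145. Upper-layer genes had 2 of 10 above 0 (adjusted p = 0.0467, and adjusted p = 0.715 with an estimated correlation). Otof had -0.18 ± 0.070, Pou3f3 -0.12 ± 0.060 and Pou3f2 -0.11 ± 0.063. Atf4 is the only member of the lists named for lithium in WT, apart from Ctnnb1 among the autism risk genes, that passed over all genes.

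limma called 5 genes for lithium in WT (1558 at an unadjusted p under 0.05), edgeR 6 and DESeq2 39, upper-quartile rescaling gave 0 higher and 3 lower, and in each sex alone limma called 0, with 978 and 755 at an unadjusted p under 0.05, 0 by edgeR and 0 and 1 by DESeq2. The count was 0 without WT lithium female 1 or 2, WT lithium male 1 or 4, WT vehicle female 1, 2, 4 or 5 or WT vehicle male 1, 4 or 5, 1 without WT lithium male 2, 2 without WT vehicle male 3, 8 without WT lithium male 3, 9 without WT vehicle male 2, 10 without WT vehicle female 3, 14 without WT lithium female 3 and 44 without WT lithium female 4.

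Whether a drug acted differently in HT and WT was tested by the interactions, and no gene passed in either. For fluoxetine the values with the smallest p were -0.80 ± 0.184 for Star, which carries cholesterol into mitochondria, -0.93 ± 0.235 for the cytokine receptor gene Csf2rb2 and -0.29 ± 0.077 for Zfp13, with adjusted p-values of 0.643, 0.964 and 0.964. Immediate early genes lay lower for fluoxetine in HT than in WT, with 4 of 20 above 0 and a median of -0.44 (camera adjusted p = 0.0134, and adjusted p = 0.996 with an estimated correlation). For lithium the values were -0.14 ± 0.039 for Kctd3, -0.45 ± 0.126 for Ntsr1 and -0.30 ± 0.084 for Akr1b10, each with an adjusted p of 0.998.

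With lithium, 11 lists differed between the genotypes by the preset test. Higher in HT than in WT were the lithium effects on the choroid plexus list, with a median difference of 0.78 (adjusted p = 2.14e-05, and adjusted p = 0.736 with an estimated correlation), leptomeningeal genes with 0.093 (adjusted p = 0.0203, and adjusted p = 0.736 with an estimated correlation) and interferon response genes with 0.15 (adjusted p = 0.00532, and adjusted p = 0.736 with an estimated correlation). The same held for ribosomal protein genes with 0.031 (adjusted p = 0.00532, and adjusted p = 0.797 with an estimated correlation), oxidative phosphorylation with 0.031 and cholesterol genes with 0.057 (adjusted p = 0.0203 and, with an estimated correlation, adjusted p = 0.797 for both). In females alone the ribosomal (adjusted p = 6.36e-12), oxidative phosphorylation (adjusted p = 0.0307) and interferon lists (adjusted p = 0.0399) went the other way, and in males alone the cholesterol list did (adjusted p = 0.243), and the differences between the sexes were not tested for the interactions. The choroid plexus list rests on HT lithium male 1 and WT vehicle female 4: without both its adjusted p was 0.591, and with the dissection covariates, of which its own score is 1, it reversed (adjusted p = 0.768). Lower were the unfolded protein response, with none of 18 genes above 0 and a median of -0.13 (adjusted p = 1.27e-05, and adjusted p = 0.736 with an estimated correlation), presynaptic genes with -0.061 (adjusted p = 0.0103, and adjusted p = 0.736 with an estimated correlation) and the excitatory postsynapse with -0.038 (adjusted p = 0.0368, and adjusted p = 0.736 with an estimated correlation). Deep-layer neuron genes had a median of -0.096 (adjusted p = 0.0457, and adjusted p = 0.736 with an estimated correlation) and autism risk genes of -0.041 (adjusted p = 0.0457, and adjusted p = 0.797 with an estimated correlation). No member of these lists passed over all genes, and adjusted over the list alone 1 deep-layer gene fell.

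For the fluoxetine interaction limma called 0 genes, with 793 at an unadjusted p under 0.05, edgeR 0 and DESeq2 1. For the lithium interaction limma called 0, with 609 at an unadjusted p under 0.05, edgeR 0 and DESeq2 4, and in females alone the fluoxetine interaction gave 2.

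The sex differences of the other effects passed for no gene. For the genotype effect the female minus male values with the smallest p among named genes were 0.41 ± 0.095 for Jund, 0.69 ± 0.162 for Trir and 0.41 ± 0.099 for Zfp653, each with an adjusted p of 0.459. For fluoxetine in HT they were 1.56 ± 0.376 for the nitric oxide synthase gene Nos2, -0.99 ± 0.242 for Rom1 and -1.39 ± 0.340 for the DNA repair gene Fanci, each with an adjusted p of 0.87. For lithium in HT they were -0.39 ± 0.099 for Zfp653, -0.42 ± 0.114 for Uqcc2 and 0.55 ± 0.152 for Gpr165, and for lithium in WT -1.52 ± 0.406 for Crybg2, 0.86 ± 0.237 for Wnt5b and -0.62 ± 0.177 for Nr6a1, each with an adjusted p of 1. limma called 0 genes in these 4 comparisons, with 715, 836, 519 and 303 at an unadjusted p under 0.05, edgeR called 0 in each and DESeq2 5, 3, 2 and 0.

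Lithium's fall of Ctnnb1 and of Ppp1r21 and its rise of Atf4 were called in both genotypes. Independent lists of these sizes would share 0.0065 genes that fell and 0.0034 that rose. Of the 64 genes called for lithium in HT, 62 lay on the same side in WT and 30 of these had an unadjusted p under 0.05 there, with a median ratio of the log2 changes of 0.42. Of the 5 called in WT, 5 lay on the same side in HT and 3 had an unadjusted p under 0.05. For fluoxetine, 56 of the 61 genes called in WT lay on the same side in HT and 19 had an unadjusted p under 0.05, with a median ratio of 0.34. A ratio below 1 is partly built in, since genes were selected on 1 side.

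Correlations of the log2 changes across the 16606 genes, which are not independent replicates, were computed for 6 pairs of effects, each beside 100 simulated sets without any effect. Between HT and WT, which share no library, r was 0.25 for fluoxetine (simulated mean -0.002, SD 0.185, and 15 of 100 draws as far from it) and 0.16 for lithium (simulated mean -0.014, SD 0.19, 38 draws). The other pairs share vehicle libraries. The genotype effect and fluoxetine in HT gave -0.38 (simulated mean -0.50, SD 0.135, 41 draws), and the genotype effect and lithium in HT -0.45 (simulated mean -0.51, SD 0.145, 67 draws). Both drugs against each other gave 0.40 in HT (simulated mean 0.50, SD 0.141, 45 draws) and 0.26 in WT (simulated mean 0.47, SD 0.136, 10 draws). With the shared vehicle libraries split, mean r was 0.051, -0.017, -0.036 and -0.13 for these 4 pairs. Their covariances were -0.00942, -0.01195, 0.01011 and 0.00671, beside simulated ones of -0.01252, -0.01317, 0.01235 and 0.01254. In each of the 6 pairs at least 10 of 100 draws lay as far from the simulated mean.

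No list call was made in any of the 7 comparisons for 11 lists, whose smallest adjusted p-values were these. Wnt/beta-catenin target genes had 0.171 and GABAergic interneuron genes 0.632. The inositol metabolism and GSK3 list, which holds direct targets of lithium, had 0.155, thyroid hormone response genes 0.0533 and circadian clock genes 0.147. Astrocyte genes had 0.0814, oligodendrocyte and myelin genes 0.101, immature neuron and proliferation genes 0.156, striatal neuron genes 0.092, red blood cell genes 0.32 and voltage-gated ion channels 0.0882. In the called lists the median, the mean and the test had the same sign in every comparison, and where they differed the adjusted p was at least 0.495.

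Libraries of the same group differed widely in genes of the olfactory bulb, which borders the prefrontal cortex. The mean log2(value + 1) of 10 such genes, chosen after a principal component with 19.1% of the variance was seen to be led by them, ran from 3.37 to 10.41 over the libraries. The mitral cell gene Cdhr1 was between 102.7 and 7854.2. The group means lay between 5.32 ± 2.51 in HT vehicle males and 8.85 ± 1.29 in WT fluoxetine males. With this score as a covariate limma called 5 genes for fluoxetine in HT, 184 for fluoxetine in WT, 164 for lithium in HT and 26 for lithium in WT.

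**Figure D4:**
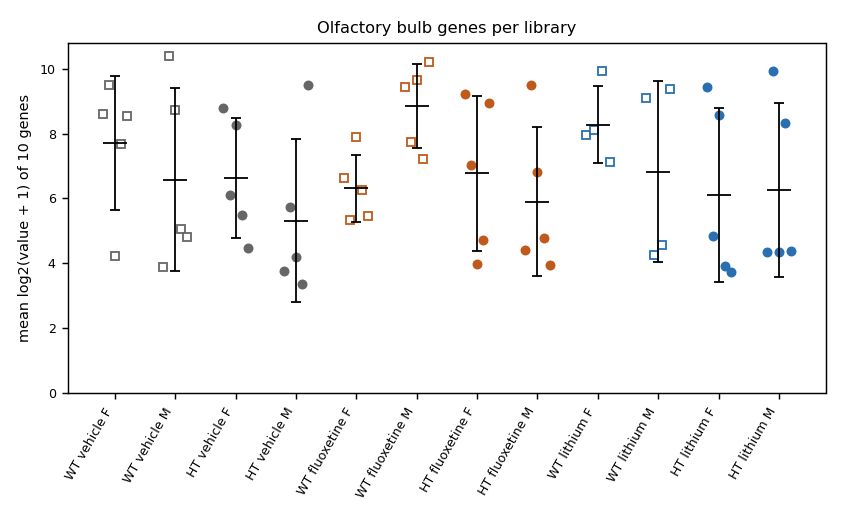
Mean log2(value + 1) of 10 olfactory bulb genes (vertical axis) in each library of the 12 groups (horizontal axis), with symbols and colours as in the earlier figures. Bars are the mean ± SD, and values between 3.37 and 10.41 occur among libraries treated alike.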

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

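The tests on other splits of the libraries, the search for a sex difference among the genes called in WT females, the olfactory bulb covariate, the removal of GC and length trends, and the comparison of lithium with fluoxetine were chosen only after the results were seen, as was the limit of a group mean of 10 for the search for single distant libraries.

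The fluoxetine effect in WT was higher in females than in males, by a test of the difference itself, for Zfp771 (0.69 ± 0.129), Tmem121 (0.80 ± 0.151) and Fam171a2 (0.40 ± 0.079).

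The effects of the drugs differed between HT and WT for 12 lists by the preset list test. For fluoxetine this was the list of immediate early genes (adjusted p = 0.0134, and 0.996 with an estimated correlation). For lithium the adjusted p-values were 2.14e-05 for choroid plexus, 1.27e-05 for the unfolded protein and integrated stress response, 0.00532 for interferon response and for ribosomal proteins, and 0.0103 for the presynapse. They were 0.0203 for leptomeningeal genes, cholesterol synthesis and oxidative phosphorylation, 0.0368 for the postsynapse, and 0.0457 for deep-layer neurons and autism risk genes. With an estimated correlation the adjusted p was 0.736 or 0.797 for each of these 11 lists.

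Single libraries lay far from the other 3 or 4 of their group in 81 of 1007 searches of a named gene in a group, or 8%. The measure was the gap to the nearest library divided by the range of the group, and chance alone marks about 1 in 20 groups. Of the 58 libraries 37 were concerned at least once, with WT fluoxetine female 1 at 8 times and HT lithium male 1 and HT vehicle male 5 at 6 times each. The ratio stands in brackets after each gene, and 2 of the 81 cases are left out of the text. HT fluoxetine female 4 held the highest values of Gkn3 (0.907), Rpl17 (0.794) and Rom1 (0.741) and the lowest values of Tcf4 (0.713) and Zfp275 (0.719). HT fluoxetine female 5 held the highest values of Npas4 (0.896), Btg2 (0.742) and Klhdc9 (0.788) and the lowest value of Calr (0.754). HT fluoxetine male 1 held the highest value of Arc (0.73) and the lowest value of Ddx3y (0.745). HT fluoxetine male 2 held the lowest value of Pou3f3 (0.713). HT fluoxetine male 4 held the lowest value of Rom1 (0.851). HT fluoxetine male 5 held the highest value of Cdh5 (0.713).

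HT lithium female 1 held the lowest value of Syn1 (0.781). HT lithium female 2 held the highest values of Rpl14 (0.797) and Clic6 (0.743). HT lithium female 3 held the highest values of Ddx3y (0.985), Kdm5d (0.982) and Eif2s3y (1). HT lithium male 1 held the highest values of Prlr (0.936), Car12 (0.77), Clic6 (0.971), Sostdc1 (0.948) and Xist (0.817) and the lowest value of Rab34 (0.715). HT lithium male 2 held the highest value of Sult1a1 (0.746) and the lowest value of Rims1 (0.729). HT lithium male 4 held the highest value of Ptprz1 (0.852). HT lithium male 5 held the highest values of Napepld (0.733), Calb1 (0.776) and Armcx5 (0.753) and the lowest value of Aoc2 (0.73).

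HT vehicle female 1 held the highest value of Nlgn3 (0.744). HT vehicle female 2 held the highest value of Vamp2 (0.74) and the lowest value of Xist (0.846). HT vehicle female 4 held the highest value of Sgk1 (0.797). HT vehicle female 5 held the highest value of Clic6 (0.725) and the lowest value of Atp5g3 (0.797). HT vehicle male 2 held the highest value of mt-Nd4l (0.72). HT vehicle male 3 held the highest values of Btg2 (0.739) and Pcdhga12 (0.807). HT vehicle male 4 held the highest value of mt-Nd3 (0.847) and the lowest value of Tmem72 (0.749). HT vehicle male 5 held the highest values of Tbl1x (0.759), Aqp1 (0.907), Htr5b (0.792), Fkbp5 (0.72) and Calr (0.731) and the lowest value of Cplx2 (0.797).

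WT fluoxetine female 1 held the highest values of Calr (0.79), Lfng (0.714), Homer1 (0.767), Nr4a3 (0.785) and Ptch1 (0.821) and the lowest values of Cdh10 (0.852), Klhdc9 (0.714) and Slc6a15 (0.728). WT fluoxetine female 2 held the highest value of Unc5c (0.726). WT fluoxetine female 5 held the lowest value of Myh11 (0.779). WT fluoxetine male 1 held the highest values of Calr (0.734) and Pdia6 (0.736). WT lithium female 4 held the highest values of Vwf (0.962) and Sec24d (0.884). WT lithium male 1 held the lowest value of Ogn (0.921). WT lithium male 2 held the lowest value of Ntsr1 (0.878). WT lithium male 3 held the highest value of Armcx5 (0.844) and the lowest value of Zfp275 (0.839). WT vehicle female 3 held the highest values of mt-Atp6 (0.712) and Egr3 (0.793). WT vehicle female 4 held the highest values of Prlr (0.97), Tmem72 (0.923), Rps24 (0.742), Ogn (0.818) and Oas1a (0.795). WT vehicle male 1 held the lowest value of Trir (0.722). WT vehicle male 2 held the highest value of Ddx3y (0.803). WT vehicle male 4 held the highest value of Ppp1r21 (0.747). WT vehicle male 5 held the highest value of Map3k6 (0.848).

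Fluoxetine called 155 genes in WT females and 0 in WT males by limma, with 1199 at an unadjusted p under 0.05 in males, 0 by edgeR and 2 by DESeq2. Different amounts of olfactory bulb tissue in the dissections are argued against as the whole source, since with that score as a covariate 212 genes were called in females, 148 of the 155 among them. GC content and transcript length bias between libraries may be the source: with the trend of each library removed, 2 of the 155 genes were called, as their median absolute change went from 0.26 to 0.17 while their median SE went from 0.063 to 0.060. The genes that rose had a median GC content of 58.7%, those that fell 41.6% and all tested genes 49.4%, and a response that itself follows GC content would be removed alike. A difference in the fluoxetine response between the sexes stays open, as 3 of the 155 genes passed the test of that difference, while 94 had the same direction in males with a median male change, signed by the females, of 0.024.

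Ctnnb1 fell with lithium in HT and in WT. Different amounts of olfactory bulb tissue are argued against as the whole source, since the smaller of both changes was -0.20 ± 0.038 in WT with that covariate (adjusted p = 0.0156). GC content and transcript length bias is argued against in the same way by -0.18 ± 0.040 in WT with the trends removed (adjusted p = 0.0428), and over 18 alternatives the adjusted p in WT ran from 0.00167 to 0.711. A response to lithium itself is a hypothesis that these values allow. Lithium minus fluoxetine, where vehicle libraries enter only the SE, was -0.24 ± 0.037 in HT and -0.24 ± 0.039 in WT. Leaving out single libraries kept the call in WT in 6 of 18 cases and that in HT in 20 of 20.

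Tbl1xr1, Tbl1x and Gm43672 were higher in HT. Reads shared between the paralogs are argued against, since 0% of the 31-base words of Tbl1x transcripts occur in those of Tbl1xr1. Different amounts of olfactory bulb tissue are argued against by 0.28 ± 0.032 for Tbl1xr1, 0.20 ± 0.028 for Tbl1x and 0.38 ± 0.060 for Gm43672 with that covariate. A strain variant in the segment around Tbl1xr1 cannot be told apart from the knock-in allele for Tbl1xr1 and Gm43672, since it would be inherited together with it. Within 10 megabases to each side 4 of 50 other genes had an unadjusted p under 0.05, or 8% against 5.74% elsewhere (Fisher's exact test p = 0.533).

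Other splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included, were tested for 24 comparisons, without correction for their number. They treat libraries as exchangeable and do not separate litters, which the labels do not give. Taken singly, the share was under 0.05 for the genotype, with 3 genes against at most 1 in the other splits (1 of 100 splits as large). The same held within each sex, with 2 genes against at most 1 (1 of 100 each). A share of 1 of 100 is the smallest that 100 splits can give. At 2 of 100 each were fluoxetine in WT, with 61 genes against at most 428, and its females, with 155 against 459. So were lithium in HT, with 64 against 466, and in WT, with 5 against 34. Chance is not excluded for these, since another split called more. The sex difference of fluoxetine in WT had 3 against 327 (4 of 100). Its splits exchanged fluoxetine and vehicle within each sex. They thus stand for no drug effect in either sex, and cannot exclude chance for a difference between the sexes. In HT females lithium called 1 gene against 0 in the other splits (1 of 100), a statement on a single gene. Lithium against fluoxetine, a comparison chosen after the values were seen, had 324 genes against 5 in HT (1 of 100). In WT it had 802 against 819 (2 of 100).

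For fluoxetine in HT females the share was not under 0.05 even taken singly, with 1 gene against at most 4 (5 of 100 splits). Where limma called 0 genes all 100 splits are as large by construction, and the highest other counts were 17 for fluoxetine in HT and 2 in its males, 544 for fluoxetine in WT males, 3 for lithium in HT males, and 6 and 4 for lithium in WT females and males. They were 24 and 4 for the interactions with fluoxetine and lithium, and 3, 12, 26 and 1226 for the sex differences of the genotype, fluoxetine in HT, lithium in HT and lithium in WT. Single splits that called several times the real count, such as 428 against 61 and 466 against 64, point to a structure among the libraries, and what those splits follow was not tested.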

How the results depend on the processing

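The olfactory bulb covariate, the removal of GC and length trends, the removal of the libraries with the highest olfactory bulb scores, and the comparison of lithium with fluoxetine were chosen after the data were seen.

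Pseudocounts of 0.5 and 5, no minimum or a minimum mean of 50, edgeR and the block of library numbers left the counts of the effects over both sexes, the interactions and the sex differences within 1.5 times the reported ones. Within single sexes edgeR called 8 genes for lithium in HT males, 1 for the genotype in females and 0 for fluoxetine in HT females, where limma called 0, 2 and 1. The genotype call of Tbl1xr1 held in 18 of 18 alternatives, with changes between 0.27 and 0.32, that of Tbl1x in 15 and that of Gm43672 in 17. Map3k6 with fluoxetine in WT held in 17 of 18, between 0.86 and 1.03, and Fkbp5 in 15. Ctnnb1 with lithium held in 17 of 18 in HT, between -0.28 and -0.24, and in 13 of 18 in WT, between -0.24 and -0.15. Of 1470 values of called genes under the alternatives 1146 stayed past the threshold and 324 did not, and none reversed. Of 62 list calls, 58 held with the replicate block, 47 with the dissection covariates, 53 with the GC and length trends removed, 28 in females alone and 41 in males alone.

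The cause of the following differences was not tested, unless stated. DESeq2 called 9 genes for the genotype, 18 for fluoxetine in HT, 229 for fluoxetine in WT, 183 for lithium in HT, 39 for lithium in WT, 1 and 4 for the fluoxetine and the lithium interaction, and 5, 3, 13 and 2 for the sex differences of the genotype, fluoxetine in HT, fluoxetine in WT and lithium in HT. Array weights gave 6 for the genotype, 3 and 859 for fluoxetine in HT and WT, 109 and 284 for lithium in HT and WT, 325 for the sex difference of fluoxetine in WT and 1925 for lithium against fluoxetine in WT. Upper-quartile rescaling gave 3 for lithium in WT, and median centring 37 for fluoxetine in WT and 0 for lithium in WT. The replicate block gave 508 for lithium against fluoxetine in WT, although libraries with the same number were no closer (mean r -0.003 against 0.001).

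Dissection covariates gave 3 and 98 for fluoxetine in HT and WT, 12 for lithium in WT and 0 for the sex difference of fluoxetine in WT. They reversed the choroid plexus list, whose own score is a covariate, to an adjusted p of 0.825 for the genotype, 0.803 for lithium in HT and 0.768 for the lithium interaction. With the olfactory bulb covariate, 5 and 184 genes were called for fluoxetine in HT and WT, 164 and 26 for lithium in HT and WT, 0 for the sex difference of fluoxetine in WT, and 617 and 1223 for lithium against fluoxetine in HT and WT. With GC and length trends removed there were 6 for the genotype, 4 and 21 for fluoxetine in HT and WT, 13 for lithium in WT, 0 for the sex difference of fluoxetine in WT and 524 for lithium against fluoxetine in WT.

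Fewer libraries were compared in the next settings. Without the libraries with the highest olfactory bulb scores there were 4 for fluoxetine in WT, 24 and 0 for lithium in HT and WT, 19 for the sex difference of fluoxetine in WT, and 206 and 20 for lithium against fluoxetine in HT and WT. Only the groups of a comparison gave 11 for fluoxetine in WT, 16 and 0 for lithium in HT and WT, 0 for the sex difference of fluoxetine in WT, and 193 and 100 for lithium against fluoxetine in HT and WT. Females alone gave 1 and 155 for fluoxetine in HT and WT, 1 and 0 for lithium in HT and WT, 2 for the fluoxetine interaction and 6 for lithium against fluoxetine in HT. Males alone gave 0 for fluoxetine in WT, 0 for lithium in HT and in WT, and 20 and 0 for lithium against fluoxetine in HT and WT. With an estimated correlation 1 of the 62 lists was called.

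In females alone some results reversed. The correlation across genes of fluoxetine in HT and WT was -0.026. The log2 changes were 0.025 for Calr and 0.022 for Hspa5 with fluoxetine in HT, 0.057 for Egr3 and 0.009 for Nr4a3 with fluoxetine in WT, and -0.14 for Sostdc1 with lithium in HT. Lists reversed to an adjusted p of 0.163 for the unfolded protein response and for ribosomal proteins with fluoxetine in HT, and of 7.32e-05 for ribosomal proteins with lithium in HT. In the lithium interaction the values were 6.36e-12 for ribosomal proteins, 0.0307 for oxidative phosphorylation and 0.0399 for interferon response. In males alone the choroid plexus list reversed for the genotype (0.919) and cholesterol synthesis in the lithium interaction (0.243).

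Leaving out 1 library at a time gave between 3 and 4 genes for the genotype, 0 and 2 for fluoxetine in HT, 18 and 347 for fluoxetine in WT, 25 and 84 for lithium in HT and 0 and 44 for lithium in WT. It gave 0 for both interactions and for the sex differences other than that of fluoxetine in WT, which had between 0 and 52. The counts for lithium against fluoxetine lay between 210 and 482 in HT and between 342 and 1498 in WT, and between 49 and 67 lists were called. The correlations ran from -0.51 to -0.27 and from -0.56 to -0.34 for the genotype with fluoxetine and lithium in HT, from 0.20 to 0.28 and from 0.11 to 0.21 between the genotypes for fluoxetine and lithium, and from 0.35 to 0.48 and from 0.20 to 0.37 between the drugs in HT and WT.

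Depth was not varied in simulated data, so what it limits was not tested apart from the spread and number of libraries. With many genes changed at this depth, 54% to 75.5% at 1.3-fold and 85.7% to 100% at 2-fold were called in the genotype simulation, in which genes varied independently.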

Other observations

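The comparison of lithium with fluoxetine, the rule for the genes named in it and its list tests, the olfactory bulb score the list tests of the sex differences and the removal of HT lithium male 1 from a list test were chosen after the values were seen.

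Lithium was compared with fluoxetine in each genotype. Vehicle libraries enter only the SE and p-values. Gadd45b, a stress and activity gene, was higher with lithium by 0.65 ± 0.145 in HT (adjusted p = 0.0101, 10 of 10 libraries) and by 0.51 ± 0.153 in WT (adjusted p = 0.0431, 7 of 8). The Notch target Hes1 was higher by 0.46 ± 0.115 and 0.41 ± 0.122, the hedgehog receptor gene Ptch1 by 0.40 ± 0.087 and 0.33 ± 0.092, Ier5l by 0.64 ± 0.120 and 0.42 ± 0.128 and Aoc2 by 0.48 ± 0.136 and 0.47 ± 0.145. Rbm28 was higher by 0.24 ± 0.067 and 0.36 ± 0.072, Zfp275 by 0.30 ± 0.053 and 0.26 ± 0.056 and the ciliary gene Ift80 by 0.16 ± 0.042 and 0.28 ± 0.044. Frat1, which encodes a GSK3-binding protein of the Wnt pathway, had -0.53 ± 0.132 in HT (adjusted p = 0.0229, 9 of 10 libraries) and -0.59 ± 0.140 in WT (adjusted p = 0.0133, 8 of 8). Ctnnb1 had -0.24 ± 0.037 (adjusted p = 0.000212, 10 of 10) and -0.24 ± 0.039 (adjusted p = 0.000427, 8 of 8). Lower in both were also Klhdc9 (-0.44 ± 0.113 and -0.41 ± 0.120), the kinase gene Pnck (-0.29 ± 0.068 and -0.38 ± 0.072), Flrt3 (-0.33 ± 0.077 and -0.30 ± 0.082), the amino acid transporter gene Slc6a15 (-0.28 ± 0.061 and -0.27 ± 0.065), Armcx5 (-0.31 ± 0.068 and -0.23 ± 0.072) and Sec24d (-0.22 ± 0.057 and -0.24 ± 0.060).

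All 20 immediate early genes were higher with lithium than with fluoxetine in HT, with a median of 0.67 (adjusted p = 9.48e-13, and adjusted p = 0.488 with an estimated correlation). Of these 7 passed over all genes and 14 adjusted over the list alone, and Arc had 1.64 ± 0.375. In WT 19 of 20 were higher, 3 passed over all genes and 4 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.000136, and 0.995 with an estimated correlation). The unfolded protein and integrated stress response was higher in WT, with 18 of 18 above 0, 9 past the threshold over all genes and 13 adjusted over the list alone (adjusted p = 6.04e-12, and adjusted p = 0.302 with an estimated correlation). Calr had 0.24 ± 0.050 there and Sdf2l1 0.46 ± 0.136. Ribosomal proteins were lower in WT, with 7 of 81 above 0 and none past the threshold (adjusted p = 1.14e-07, and 0.995 with an estimated correlation).

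In HT 20 of 21 cholesterol genes were higher, 1 past the threshold over all genes and 5 adjusted over the list alone (adjusted p = 3.49e-06, and 0.977 with an estimated correlation). Presynaptic genes were lower, with 4 of 19 above 0, 2 that passed over all genes and 5 adjusted over the list alone (adjusted p = 0.00235, and 0.977 with an estimated correlation). Choroid plexus genes were higher, with 10 of 10 above 0 and none past the threshold (adjusted p = 0.0223, and 0.977 with an estimated correlation). Without HT lithium male 1 the adjusted p of this list was 0.687.

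limma called 324 genes between the drugs in HT, of which 154 were higher with lithium and 170 lower, with 2543 at an unadjusted p under 0.05, edgeR 293 and DESeq2 449. In WT it called 802, 435 higher and 367 lower, with 3382 at an unadjusted p under 0.05, edgeR 785 and DESeq2 1093. The count in WT was 524 with the GC and length trends removed, 100 with only the groups of the comparison and 20 without the libraries with the highest olfactory bulb scores, and its differences had r = -0.17 with GC content across genes, which are not independent replicates. Of the 51 called in both, 18 were higher in both, 32 lower in both and 1 opposite, where independent lists would share 4.03 and 3.76. Centring on the median gave 105 higher and 250 lower in HT, and upper-quartile rescaling 311 higher and 455 lower in WT. In WT 861 genes were called in females and 0 in males by limma, with 2028 in males at an unadjusted p under 0.05.

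Without HT lithium male 3 the count in HT was 210. In WT it was 342 without WT lithium female 1, 353 without WT fluoxetine male 5, 386 without WT fluoxetine male 2, 395 without WT lithium female 2, 413 without WT lithium male 4, 435 without WT lithium male 2, 470 without WT fluoxetine female 3, 501 without WT fluoxetine female 5, 1267 without WT lithium female 4 and 1498 without WT fluoxetine male 1.

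The list tests of the sex differences called 7 lists for the genotype, 8 for fluoxetine in HT and 6 each for fluoxetine in WT, lithium in HT and lithium in WT, and none of these held with an estimated correlation.

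The scores of olfactory bulb, GC slope and length slope were compared in 30 tests within each sex. The smallest exact permutation p, 0.00794, was that of the GC slope of WT fluoxetine females (0.0562 ± 0.0327) against WT vehicle females (-0.013 ± 0.0174), with an adjusted p of 0.238. It is the smallest that 5 against 5 libraries can give, so alone among 30 tests it could not pass, and the lowest slope of the fluoxetine females, 0.0079, lay above the highest of the vehicle females, 0.0064.

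HT lithium female 3 had 66.7 for Ddx3y, 55.4 for Kdm5d, 21.6 for Uty and 87.2 for Eif2s3y, or 3.8%, 5.92%, 4.52% and 6.79% of the male means, where the highest other female had 1.3, 3.7, 3.4 and 1.2. Among males, Eif2s3y was 211 in WT lithium male 4 and 388.3 in WT fluoxetine male 1, against a male mean of 1285.5, while their Ddx3y was 1747.1 and 1968.1.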
